A study of Mus musculus with 23 samples.

How the data were processed

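RNA of CD103+ cDC1 from control and PGE2-deficient melanomas was measured by Smart-seq3 on pools of 10 sorted cells, with up to 3 pools from each of 8 mice. Per the labels, tumours were digested with collagenase and DNase, immune cells were enriched on a density gradient and cells were sorted directly into lysis buffer. The authors deposited a table of counts, whole numbers per gene and library without normalization. The submitters' processing notes name the aligner STAR (version 2.5.4b) and the mouse genome build GRCm38 (mm10). The counting program, the annotation, any filter on genes and whether reads or unique molecular identifiers were counted are not given in the sources used here. Because amplified reads are not independent molecules, the floors given for counts of 0 and the interval given for Isg15 cover counting error only.

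The table held 13572 gene rows, of which 261 had no count. By identifier 13556 rows were found in GENCODE M21 (GRCm38), and 13467 carried the same symbol there. A further 16 symbols had been turned into dates by a spreadsheet program and were replaced through their identifiers. Protein-coding genes held 76.32% of the counts and 2067 pseudogene rows 11.26%. The top row, a ribosomal RNA-like gene, held 6.27%. No 2 libraries were duplicates, since the chi-squared statistic per degree of freedom between libraries was 2.17 or more. The values contain no spike-in reference, so all levels are relative to the other genes of a library. PGE2-deficient mouse 2 had 2 libraries.

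Libraries of a mouse, which the labels call technical replicates, were summed, giving 4 mice against 4. Mouse numbers recur in both groups, but they were not treated as pairs. Deviations from the group mean correlated between mice of the same number by −0.089 to 0.1, and 0 of the 4 numbers correlated best with their own counterpart. Genes were filtered with filterByExpr (minimum count 10), which left 2076 genes with 80.6% of the counts. They were tested with the quasi-likelihood F-test of edgeR 4.0.16 (TMM scaling, two-sided, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05). The common biological coefficient of variation was 21.8%. CPM are counts scaled by TMM-adjusted totals over tested genes. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Gene lists were tested with camera on the same fit (limma 3.58.1, preset correlation 0.01) and adjusted over the 19 lists with at least 3 tested members, beside camera with an estimated correlation and fry. Scores and library measures were compared by exact two-sided permutation over all 70 assignments of the 8 mice. DESeq2 1.42.0 served as an alternative. Calculations ran in R 4.3.3 and Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

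The tests, the 30 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took up to 12 called genes per direction with the largest fold change among those with separated groups, leaving out predicted genes and antigen receptor segments. It added a fixed panel of dendritic cell, interferon and prostaglandin genes whatever their result. It further took up to 4 called members per list (or up to 2 with the smallest p where none was called) and the 2 most abundant members of each list of another cell type. The lists covered cDC1 identity, maturation, cytokines for T cells, type I and gamma interferon responses, MHC class I and II presentation, cyclic AMP and PGE2 targets, prostaglandin genes, NF-kB targets, hypoxia, the unfolded protein response, cholesterol synthesis, the cell cycle, apoptosis, dissociation stress, mitochondrial and nuclear respiratory genes and 12 other cell types. Some genes are in more than 1 list, so the lists are not independent. Marker sets for macrophages, pDC, T cells and cDC2, the alternative without libraries holding 10 or more counts of the first 3 sets (6 control libraries and 3 of the other group), thinning of the mice to 101017 counts and removal of mitochondrial and ribosomal RNA rows were added after the data were seen.

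The edgeR test was tried on simulated data with the depths of these mice and their common spread, in 10 simulations with 200 changed genes each. It recovered 51.8% of 2-fold and 84.0% of 4-fold changes, with 3.3% of its calls false and 0 calls without changed genes. DESeq2 recovered 37.7% and 90.0%. Camera called a raised list in 10 of 10 simulations and a flat list in 0. Simulated genes were drawn independently and all with the same spread. These rates therefore do not cover genes that vary more between mice, or lists with correlated members. The alternatives tried were other scaling factors, other count filters, DESeq2, robust dispersion, and limma-trend on library means. Further ones were limma-voom over libraries with the mouse as random effect, libraries as if independent, technical replicates 2 and 3 alone, the mouse number as a block, other pseudocounts for scores and leaving out each mouse. In the limma-voom fit the correlation between libraries of a mouse was estimated at −0.001, so it treated the 23 libraries nearly as independent. The labels also mention mice lacking the PGE2 receptors on cDC1, but all 23 libraries are labelled as from wild-type mice, so the labels leave open whether such mice belong to this series.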

Results

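Type 1 conventional dendritic cells (cDC1) are the subset specialised in presenting tumour antigen to CD8 T cells. They were profiled by RNA sequencing after isolation from melanomas whose cancer cells either had or lacked the enzymes that start the synthesis of prostaglandins, among them prostaglandin E2 (PGE2). Tumours were grown in wild-type C57BL/6 mice from a BRAFV600E melanoma line. One group of mice carried control tumours, and the other carried tumours whose cancer cells lacked Ptgs1 and Ptgs2, the genes of both cyclooxygenases that start prostaglandin synthesis. The latter tumours are called PGE2-deficient here, although these data hold no PGE2 level and cells of the wild-type mice keep both genes. Cells were sorted 6 days after injection as live CD45+ MHC-II+ CD11c+ CD103+ CD11b− cells, in pools of 10 cells per library. Libraries were made by Smart-seq3, a full-length method for very small inputs. There were 4 mice per group and up to 3 pools per mouse, giving 12 control libraries and 11 libraries from PGE2-deficient tumours. The mouse was the unit of replication in the main tests.

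The deposited table held 1152561 counts in 13572 gene rows. Libraries held between 25571 and 98554 counts, with a median of 49506. Mice held between 101017 and 230478 after their libraries were summed. Between 4631 and 8868 genes were detected per library. Libraries from control tumours held 45240 ± 6823 counts (mean ± SD of the mouse means, n = 4) against 55015 ± 14743 (n = 4) in the other group (exact permutation test, two-sided, p = 0.286). They detected 6177 ± 441 against 6942 ± 723 genes (exact p = 0.114). Mitochondrial transcripts made up 5.30% ± 0.868 of the counts in the control group and 4.10% ± 0.578 in the PGE2-deficient group (exact p = 0.0571). The 50 most abundant genes held 31.1% ± 2.14 and 28.4% ± 2.68 (exact p = 0.143), and the single most abundant row 6.92% and 6.15% (exact p = 0.629). None of these 5 measures passed the Benjamini-Hochberg adjustment (adjusted p from 0.238 to 0.629). The median Spearman correlation was 0.654 over the 22 pairs of libraries from the same mouse, 0.65 over 99 pairs from other mice of the same group and 0.619 over 132 pairs from different groups. Pools of the same mouse thus differed from each other about as much as pools of different mice of a group.

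The comparison of the 2 groups asks how the loss of both cyclooxygenases in the cancer cells is reflected in the transcriptome of intratumoural cDC1. In cells from PGE2-deficient tumours, Ccl5, a chemokine that attracts T cells, rose from 23.8 ± 21.3 to 1920 ± 2003 CPM (scaled counts, mean ± SD, n = 4 mice each). Its log2 fold change was 6.16 ± 0.70 (SE; adjusted p = 1.54e-05). Of genes induced by interferon, some were higher and others lower. Ifi27l2a rose from 318 ± 93.8 to 1630 ± 448 CPM (log2 fold change 2.38 ± 0.23, adjusted p = 2.03e-06), and Isg15, a ubiquitin-like modifier, from 72.4 ± 46.2 to 424 ± 99.8 CPM (2.58 ± 0.37, adjusted p = 0.000237). Xcr1, the chemokine receptor that marks cDC1, rose from 73.3 ± 46.5 to 318 ± 59.1 CPM (2.16 ± 0.38, adjusted p = 0.00242). In the other direction, Ifitm1, an interferon-induced membrane protein, fell from 7110 ± 731 to 561 ± 432 CPM (−3.69 ± 0.34, adjusted p = 1.61e-06). Il1r2, the decoy receptor for interleukin-1, fell from 707 ± 179 to 87.6 ± 68.5 CPM (−2.91 ± 0.35, adjusted p = 2.79e-05). Il1b, which encodes interleukin-1 beta itself, fell from 2097 ± 500 to 721 ± 88.2 CPM (−1.55 ± 0.18, adjusted p = 1.55e-05). In GRCm38, Ccl5 (ENSMUSG00000035042) lies on the minus strand of chromosome 11 from 83525778 to 83530518. Ifitm1 (ENSMUSG00000025491) lies on the plus strand of chromosome 7 from 140967221 to 140969825. Both are annotated as protein-coding.

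Of 2076 genes with enough counts to test, 56 were higher and 47 lower with PGE2-deficient tumours at an adjusted p under 0.05 (edgeR quasi-likelihood test). Without adjustment, 389 genes had a p under 0.05. The absolute log2 fold changes of the called genes ran from 0.45 to 6.16, and 86 of the 103 had all 4 mice of one group above all 4 of the other. Among all tested genes 10.6% were separated in that way, where chance gives 2.86%. The split between the directions depended on scaling, since upper quartile factors gave 45 higher and 67 lower genes. Without the 9 libraries that held 10 or more marker counts of macrophages, plasmacytoid dendritic cells (pDC) or T cells, an alternative added after the data were seen, 18 genes were higher and 6 lower of 1131 tested. All 71 called genes that could be tested there kept their direction. Leaving out 1 mouse gave 31 to 67 higher genes, the fewest without control mouse 2. Lower genes numbered 23 to 45, with 31 without PGE2-deficient mouse 4, 25 without control mouse 2 or 4 and 23 without control mouse 3.

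**Figure D1:**
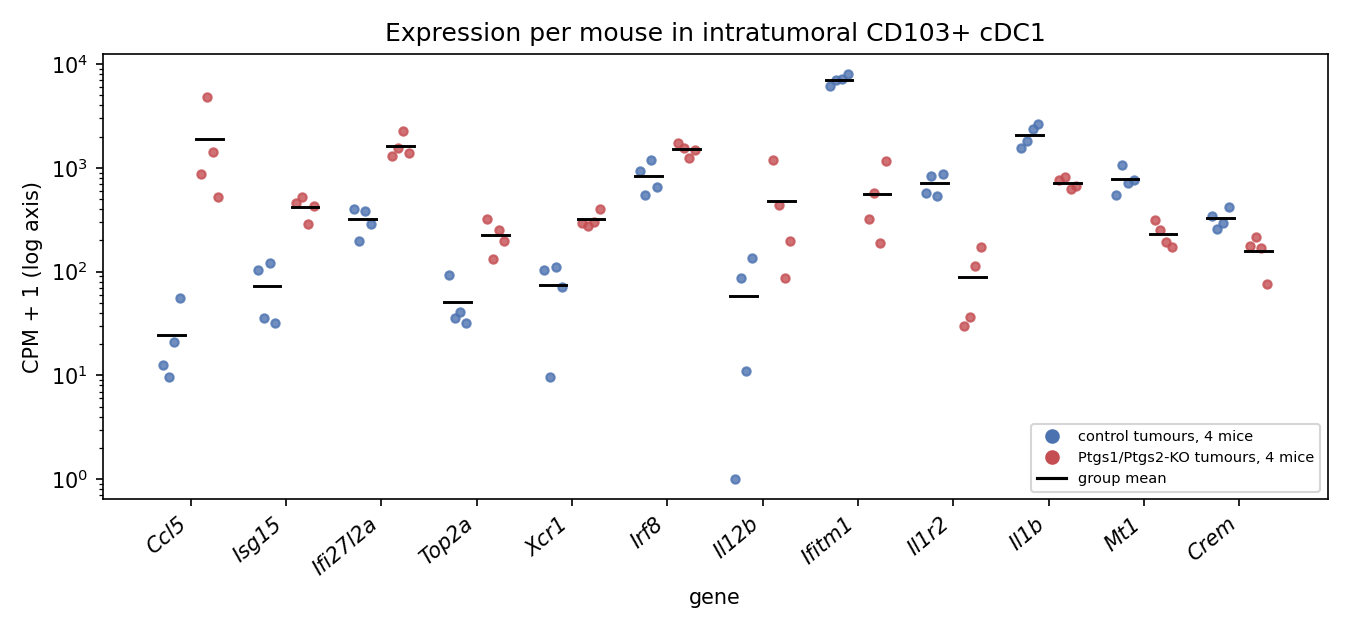
Level of 12 named genes in each of the 8 mice, as CPM + 1 on a log axis, with control tumours in blue, PGE2-deficient (Ptgs1/Ptgs2-KO) tumours in red and group means as bars. Ccl5 averages 23.8 against 1920 CPM and Ifitm1 7110 against 561 CPM without overlap, while the groups overlap for Il12b.

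Type I interferon response genes were higher as a group. Of 20 tested members 8 rose, none fell and 12 were not called (14 rose when adjusted over the list alone). All 20 had a positive fold change, with a mean log2 fold change of 1.17 (camera adjusted p = 1.51e-16; adjusted p = 0.0422 with an estimated correlation). Besides Ifi27l2a and Isg15, Phf11b rose from 91.9 ± 60.6 to 371 ± 61.7 CPM (2.04 ± 0.34, adjusted p = 0.00136). So did Ifi204, a nuclear DNA sensor of the HIN200 family, from 125 ± 67.0 to 353 ± 119 CPM (1.53 ± 0.36, adjusted p = 0.0164). Leaving out 1 mouse ended the call of Ifi204 without PGE2-deficient mouse 4 or control mouse 2 (log2 fold changes from 1.25 to 1.81). Without the 9 libraries with markers of other cells Phf11b was not called (1.77, adjusted p = 0.108). There Isg15 had 3 counts in the control group and 162 in the other, a ratio of 34.5 per total count (exact 95% interval 11.6 to 169, fitted log2 fold change 5.14, adjusted p = 0.000225). The interval pools counts over mice, so it covers counting error only and not the spread between mice. The 12 list members still tested had a mean of 1.81 (1.38 for the same genes in all libraries). The Ifitm genes, also induced by interferon, are not in this list, and all 4 tested were lower.

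Interferon gamma response genes went the same way, with 4 of 14 tested members higher (11 adjusted over the list alone), none lower and a mean log2 fold change of 1.06 (camera adjusted p = 9.66e-09; adjusted p = 0.0732 with an estimated correlation). Among the called members were 3 interferon-inducible GTPases that act against intracellular pathogens. Tgtp2 rose from 50.5 ± 18.8 to 266 ± 144 CPM (2.36 ± 0.44, adjusted p = 0.0035), Tgtp1 by 2.10 (adjusted p = 0.00851) and Ifi47 by 1.79 (adjusted p = 0.0448). Tgtp1 and Tgtp2 are near-identical neighbours, so their counts are not independent. Ifi47 kept its call in 1 of the 8 fits without a mouse (log2 fold changes from 1.35 to 1.99). Irf1 went from 65.8 ± 48.0 to 249 ± 202 CPM and was not called (1.82 ± 0.59, adjusted p = 0.0795).

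Genes of MHC class I presentation were higher in 4 of 18 tested members (10 adjusted over the list alone) and lower in none. Their mean log2 fold change was 0.65 (camera adjusted p = 1.91e-06; adjusted p = 0.105 with an estimated correlation). B2m, the invariant light chain of class I molecules, rose from 2983 ± 536 to 5486 ± 2193 CPM (0.87 ± 0.20, adjusted p = 0.0164), and H2-K1, a classical class I heavy chain, from 451 ± 74.4 to 971 ± 516 CPM (1.07 ± 0.27, adjusted p = 0.0283). The non-classical genes H2-Q6 and H2-Q7 rose by 2.18 (adjusted p = 0.0149) and 1.35 (adjusted p = 0.0497). H2-Q6 and H2-Q7 are close paralogs, whose reads are hard to tell apart. The call of B2m was lost without control mouse 1 or 2 (0.56 to 0.97 over the fits without a mouse, the lowest without PGE2-deficient mouse 2), and that of H2-K1 without PGE2-deficient mouse 2 or control mouse 2 or 3 (0.65 without the first). With robust dispersion B2m was not called (adjusted p = 0.136). Without the 9 libraries with markers of other cells B2m (1.38) and H2-K1 (1.90) had larger changes (adjusted p = 0.0208 for both). H2-Q6 lost it without control mouse 2 or 3 (1.80 to 2.52) and H2-Q7 in each of the 8 fits (1.03 to 1.46). The peptide transporter gene Tap1 went from 133 ± 46.7 to 241 ± 43.9 CPM and was not called (0.86 ± 0.30, adjusted p = 0.106).

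Genes of cDC1 identity were higher in 5 of 20 tested members (7 adjusted over the list alone) and lower in none. Their mean log2 fold change was 0.53 (camera adjusted p = 6.19e-05; adjusted p = 0.183 with an estimated correlation), and 0.34 without control mouse 2. Markers of cDC2 (305 ± 134 against 72.9 ± 65.6 CPM), macrophages (192 against 9 counts) and pDC (101 against 0 counts) had lower values with PGE2-deficient tumours. In addition to Xcr1, Irf8, the transcription factor that specifies cDC1, rose from 837 ± 296 to 1510 ± 205 CPM (0.85 ± 0.21, adjusted p = 0.0215). Naaa, a lysosomal amidase, rose from 591 ± 192 to 1254 ± 302 CPM (1.08 ± 0.23, adjusted p = 0.0104). Id2, a transcriptional repressor required for the subset, rose by 0.95 ± 0.23 (adjusted p = 0.0196), and Tlr3, the receptor for double-stranded RNA, by 1.25 ± 0.35 (adjusted p = 0.0448). Other identity genes were not called: Batf3 (0.17, adjusted p = 0.845), Clec9a (0.34, adjusted p = 0.609), Zbtb46 (0.87, adjusted p = 0.226) and Itgae, which encodes the CD103 used for sorting (0.93, adjusted p = 0.0948). Irf8 (0.68 to 1.08) and Id2 (0.77 to 1.26) both lost their call without PGE2-deficient mouse 1 or 4 or control mouse 2 or 4, and Tlr3 kept it in 2 of the 8 fits without a mouse (0.89 to 1.48). Id2 was not called with robust dispersion (adjusted p = 0.0703) or from technical replicates 2 and 3 alone (0.66, adjusted p = 0.128). Without the 9 libraries with markers of other cells Xcr1 (1.78, adjusted p = 0.185) and Irf8 (0.78, adjusted p = 0.181) were not called. Over all alternatives their adjusted p ran from 4.03e-07 to 0.185 and from 0.000365 to 0.181.

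Genes of dendritic cell maturation were higher in 4 of 16 tested members (6 adjusted over the list alone) and lower in none. Their mean log2 fold change was 0.96 (camera adjusted p = 6.19e-05). The list had an adjusted p = 0.307 with an estimated correlation, which was itself 0.586. Il12b, a subunit of the T cell-activating cytokine IL12, rose from 57.3 ± 63.6 to 481 ± 501 CPM with overlapping groups (2.86 ± 0.71, adjusted p = 0.0259). The other called members were Bcl2l14, a BCL2 family member (2.37, adjusted p = 0.0144), Cacnb3, a calcium channel subunit (1.65, adjusted p = 0.0432), and Serpinb6b, a protease inhibitor (1.45, adjusted p = 0.0466). Among better known maturation genes, Fscn1, an actin-bundling protein, went from 143 ± 52.6 to 441 ± 298 CPM (1.54, adjusted p = 0.0546). Ccr7, the receptor for migration to lymph nodes, had a log2 fold change of 0.45 (adjusted p = 0.489), Cd274 of 0.83 (adjusted p = 0.301) and the costimulatory gene Cd86 of −0.04 (adjusted p = 0.955). None of these 4 was called. The call of Il12b was lost without PGE2-deficient mouse 1 or control mouse 3 (1.82 without the former), and with DESeq2, robust dispersion and limma-voom (adjusted p of 0.132, 0.26 and 0.36, where all alternatives ran from 6.36e-14 to 0.36). The calls of Cacnb3 (1.32 to 1.90) and Serpinb6b (0.83 without PGE2-deficient mouse 2) held in 3 and 2 of the 8 fits without a mouse, and Bcl2l14 lost its call with limma-voom (1.65, adjusted p = 0.339), as did Cacnb3 (1.13, adjusted p = 0.502). Serpinb6b was not called without the 9 libraries with markers of other cells (1.81, adjusted p = 0.185) or with robust dispersion (adjusted p = 0.222). The list itself was not called from technical replicates 2 and 3 alone (0.69, adjusted p = 0.12).

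The list of cytokines and chemokines that act on T cells and NK cells had 5 tested members, of which Ccl5 and Il12b rose (2 higher and 1 lower adjusted over the list alone). The mean log2 fold change was 1.45 and the median 0.47 (camera adjusted p = 0.0279; adjusted p = 0.134 with an estimated correlation). The list call was lost without control mouse 1 and with limma-trend on library means (0.93, adjusted p = 0.193). Ccl5 counts were uneven between pools. The control group held 11 Ccl5 counts in all, at most 5 per library, whereas the PGE2-deficient group held 840. Of these 685 lay in 3 libraries, and 4 of the 11 libraries held 5 or fewer. The call was lost only with limma-voom over the libraries (log2 fold change 3.24, adjusted p = 0.365, where the adjusted p over all alternatives ran from 4.55e-83 to 0.365). Counts of the T cell receptor and CD3 genes were 11 in the control group and 56 in the PGE2-deficient group (31.6 ± 63.3 and 118 ± 106 CPM, n = 4, exact p = 0.257), and the NK and T cell effector gene Gzmb had 0 and 19 counts. Cxcl16, which encodes another T cell chemokine, was not called (0.47, adjusted p = 0.555). Cxcl9 (23 counts in the control group and 35 in the other), Cxcl10 (3 and 11) and Il15 (5 and 15) did not pass the count filter and were not tested. Nor were the costimulatory genes Cd40 (18 and 39) and Cd80 (35 and 36). Ccl22 (23 and 135) also failed the filter, with 65 and 53 of its counts in PGE2-deficient mice 1 and 2.

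Cell cycle genes were higher in 4 of 9 tested members (5 adjusted over the list alone) and lower in none. Their mean log2 fold change was 0.90 (camera adjusted p = 6.19e-05; adjusted p = 0.088 with an estimated correlation). Top2a, the topoisomerase of dividing cells, rose from 49.5 ± 28.6 to 225 ± 80.9 CPM (2.25 ± 0.40, adjusted p = 0.00245), and Hmgb2, a chromatin protein, from 208 ± 103 to 591 ± 100 CPM (1.54 ± 0.29, adjusted p = 0.00391). The tubulins Tubb5 and Tuba1b rose by 1.31 (adjusted p = 0.00469) and 0.92 (adjusted p = 0.0354). T cell marker counts were higher in the same group, as given for Ccl5. Without the 9 libraries with markers of other cells, Hmgb2 (1.46, adjusted p = 0.204), Tubb5 (1.19, adjusted p = 0.181) and Tuba1b (1.26, adjusted p = 0.0621) were not called. The list kept its call there, with a mean of 1.30 over the members still tested (camera adjusted p = 0.004). The mean of the same members in all libraries is not given, so 1.30 cannot be compared with 0.90. Top2a lost its call with limma-voom (2.13, adjusted p = 0.065), and Tuba1b held it in 3 of the 8 fits without a mouse (0.77 to 1.24). The mean of the list was 1.39 without control mouse 1.

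Of the 12 genes that the naming rule took for large increases with separated groups, 5 belong to no list. Cks1b, a cyclin-dependent kinase subunit, rose from 19.9 ± 15.2 to 126 ± 24.4 CPM (2.68, adjusted p = 0.00242). The actin-binding Lima1 rose by 2.75 (adjusted p = 0.00469), the tubulin Tubb2a by 2.24 (adjusted p = 0.00469) and the paralogous histone genes Hist1h2ao and Hist1h2ap by 2.79 and 2.44 (adjusted p = 0.0109 for both). The change of Hist1h2ao was 1.81 without PGE2-deficient mouse 1, and that of Lima1 was 4.12 without control mouse 4. The calls of Hist1h2ao and Hist1h2ap were lost with robust dispersion (adjusted p = 0.188 and 0.175), with limma-voom (0.0566 and 0.0574) and without the 9 libraries with markers of other cells (2.48, adjusted p = 0.118, and 2.24, adjusted p = 0.185).

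Immediate early and heat shock genes, which respond to tissue dissociation, had 2 of 24 tested members higher, the chaperones Hspa8 (0.66, adjusted p = 0.0196) and Hsp90aa1 (0.75, adjusted p = 0.0466). Adjusted over the list alone, 5 were higher and 2 lower, and the mean log2 fold change was 0.23 (camera adjusted p = 0.0236; adjusted p = 0.222 with an estimated correlation). The list call was lost without PGE2-deficient mouse 1 or control mouse 3, and its mean was 0.41 without PGE2-deficient mouse 3 and 0.47 without control mouse 2. The calls of Hspa8 (0.52 to 0.78) and Hsp90aa1 (0.60 to 0.89) held in 4 and 2 of the 8 fits without a mouse. Neither was called without the 9 libraries with markers of other cells (0.70, adjusted p = 0.0899, and 0.65, adjusted p = 0.249).

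Genes known to be induced by cyclic AMP or PGE2 were lower as a group. Of 12 tested members 4 fell, none rose and 8 were not called (3 higher and 8 lower adjusted over the list alone). The mean log2 fold change was −0.62 and the median −0.89 (camera adjusted p = 7.99e-05; adjusted p = 0.134 with an estimated correlation). Besides Il1b and Il1r2 these were Crem, a cyclic AMP-responsive transcription factor that fell from 329 ± 72.2 to 158 ± 59.2 CPM (−1.08 ± 0.30, adjusted p = 0.0448), and Rgs2, a regulator of G protein signalling that fell from 605 ± 58.4 to 352 ± 72.4 CPM (−0.77 ± 0.21, adjusted p = 0.0406). Nr4a1, another immediate target of the pathway, had a positive fold change without a call (0.77, adjusted p = 0.242). Crem (−1.22 to −0.86) and Rgs2 (−0.86 to −0.65) each kept their call in 2 of the 8 fits without a mouse, whereas Il1b and Il1r2 kept it in all 8. Crem (−1.20, adjusted p = 0.181) and Rgs2 (−0.99, adjusted p = 0.163) were also not called without the 9 libraries with markers of other cells. Il1b (−1.79, adjusted p = 0.00959) and Il1r2 (−3.74, adjusted p = 0.000485) stayed called there. So did the list, with a mean of −0.66 over the members still tested (camera adjusted p = 0.00547). That setting did not screen on cDC2 markers. The PGE2 receptor genes had too few counts to test, with 11 and 7 counts of Ptger2 and 31 and 24 of Ptger4 in the control and PGE2-deficient groups. The gene Ptgs2, knocked out in the cancer cells and not in the mice, had 4 and 14 counts, all 14 in 1 mouse. Il10 and Ptgs1 were not analysed here.

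The list of conventional type 2 dendritic cell (cDC2) genes had 3 of 4 tested members lower, both over all genes and adjusted over the list alone. The mean log2 fold change was −1.96 (camera adjusted p = 3.72e-10; adjusted p = 0.0232 with an estimated correlation). The 3 were Ifitm1, Il1r2 and S100a4, a calcium-binding protein that fell from 656 ± 308 to 255 ± 118 CPM (−1.33 ± 0.33, adjusted p = 0.0283). None of these is specific to cDC2, and Il1r2 is also in the list of cyclic AMP targets. S100a4 lost its call without PGE2-deficient mouse 1 or control mouse 2 or 4 (−1.54 to −1.10), and without the libraries with markers of other cells (−1.24, adjusted p = 0.313) or with robust dispersion (adjusted p = 0.0975). Without those libraries the 3 list members still tested had a mean of −3.28 (−2.64 for the same genes in all libraries). More specific cDC2 markers, chosen after the data were seen (Cd209a, Clec10a, Mgl2 and Sirpa), had 136 counts in the control group and 34 in the PGE2-deficient group, or 305 ± 134 and 72.9 ± 65.6 CPM (n = 4). The exact permutation p = 0.0286 was the smallest this design allows and did not pass adjustment over 4 marker sets (adjusted p = 0.114). The setting without libraries holding markers of other cells did not screen on these markers. It dropped control libraries with up to 25 of their counts but kept others with up to 15. Of the PGE2-deficient libraries it dropped both that held 12 and kept those with at most 3. Changes that stay or grow there therefore do not argue against cDC2-like cells.

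Markers of macrophages and pDC, also chosen after the data were seen, were found mostly in the control group, as were the lower genes. The macrophage markers C1qa, C1qb, C1qc and Apoe had 192 counts in the control group, in which 2 libraries held 10 or more, and 9 in the other (396 ± 453 and 20.3 ± 14.2 CPM, exact p = 0.4). The pDC markers Siglech, Ly6d, Klk1 and Cox6a2 had 101 and 0 counts, with 4 control libraries holding 10 or more (exact p = 0.143). A count of 0 over the group allows up to 3 counts, or 5.95 CPM. Tcf4, the transcription factor of pDC and the single tested member of their fixed list, fell from 250 ± 149 to 63.9 ± 36.0 CPM with overlapping groups (−2.08, adjusted p = 0.0163). Its call was lost without PGE2-deficient mouse 4 or control mouse 3 or 4 (−2.41 to −1.82). Of the 4 tested genes of the macrophage and monocyte list none was called (1 higher adjusted over the list alone). The list had a mean log2 fold change of −0.04, a median of −0.21 and an upward camera direction (adjusted p = 0.844). Without a count filter, which admits the markers named here, it was called lower (−2.03, adjusted p = 6.74e-08). Among them Ccr2 had a log2 fold change of 1.08 (adjusted p = 0.0536) and Lyz2 of −0.82 (adjusted p = 0.372).

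**Figure D2:**
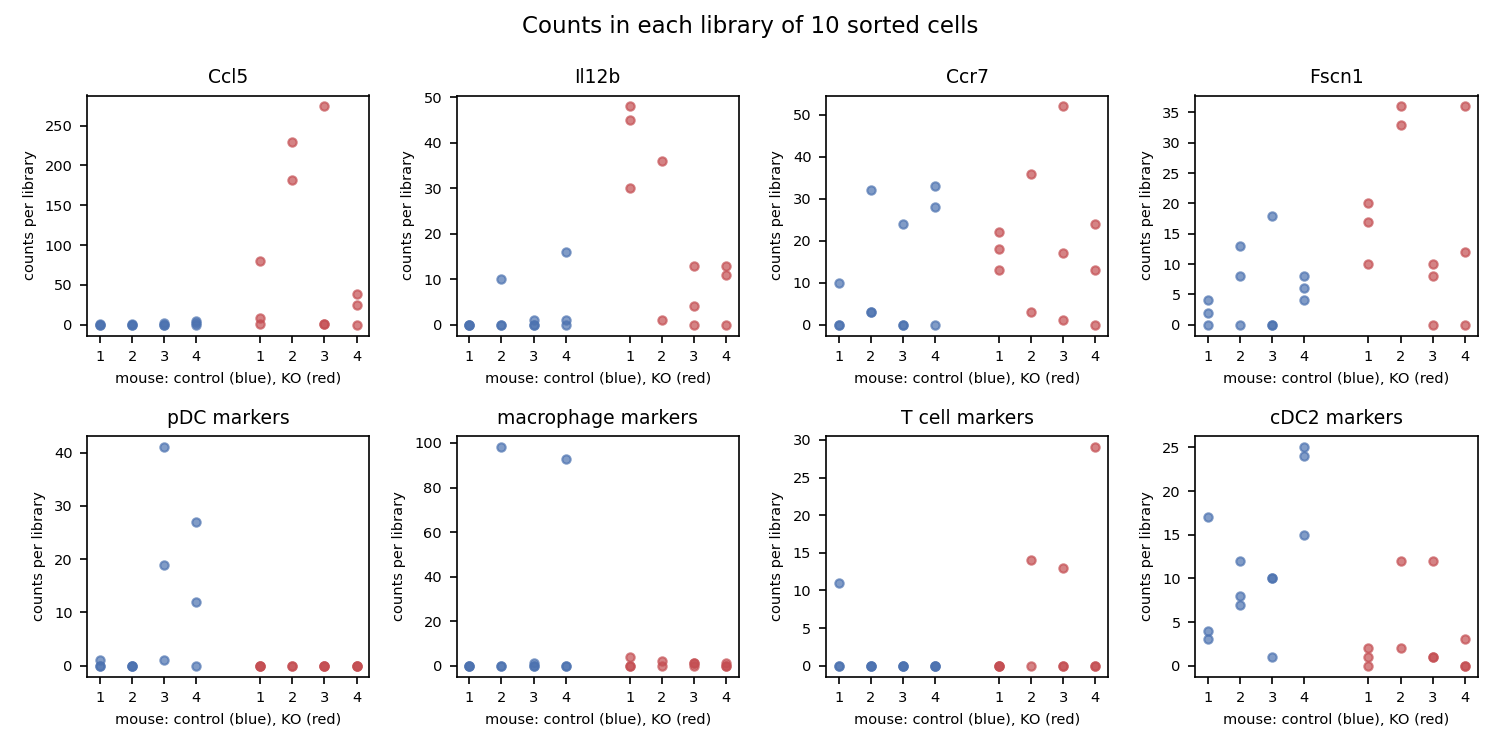
Counts of 4 genes (upper panels) and of 4 marker sets (lower panels) in each of the 23 libraries of 10 cells, by mouse, with control tumours in blue and PGE2-deficient (KO) tumours in red. Ccl5 stays at 5 counts or fewer in every control library, and pDC markers are at 0 in each of the 11 libraries of the other group.

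Among other large decreases of called genes with separated groups, Ifitm6 of the Ifitm1 family fell from 402 ± 102 to 56.0 ± 70.9 CPM (−2.84, adjusted p = 0.0022). Further lower genes were Bcl2l11, which encodes the pro-apoptotic BIM (146 ± 21.6 to 20.9 ± 10.4 CPM, −2.59 ± 0.41, adjusted p = 0.000764), and Mt1, a metallothionein (780 ± 218 to 232 ± 62.1 CPM, −1.78 ± 0.25, adjusted p = 0.000186). The receptor genes Lilr4b and Cd300a fell (−2.21, adjusted p = 0.00469, and −1.86, adjusted p = 0.00495), as did Gpr55, a lipid receptor gene (−1.77, adjusted p = 0.0146). Lower were also Hsd17b4, an enzyme of peroxisomal fatty acid oxidation (−1.66, adjusted p = 0.0466), the lectin-like receptor gene Klrb1b (−1.55, adjusted p = 0.0374) and the caspase gene Casp6 (−1.35, adjusted p = 0.0231). The calls of Gpr55 (−2.04 to −1.55), Hsd17b4 (−2.30 to −1.36) and Klrb1b (−1.98 to −1.25) held in 3, 2 and 4 of the 8 fits without a mouse. Klrb1b was also not called with robust dispersion (adjusted p = 0.102) or without the 9 libraries with markers of other cells (−1.68, adjusted p = 0.0899). That of Casp6 was lost without control mouse 3 (−1.61 to −1.15).

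**Figure D3:**
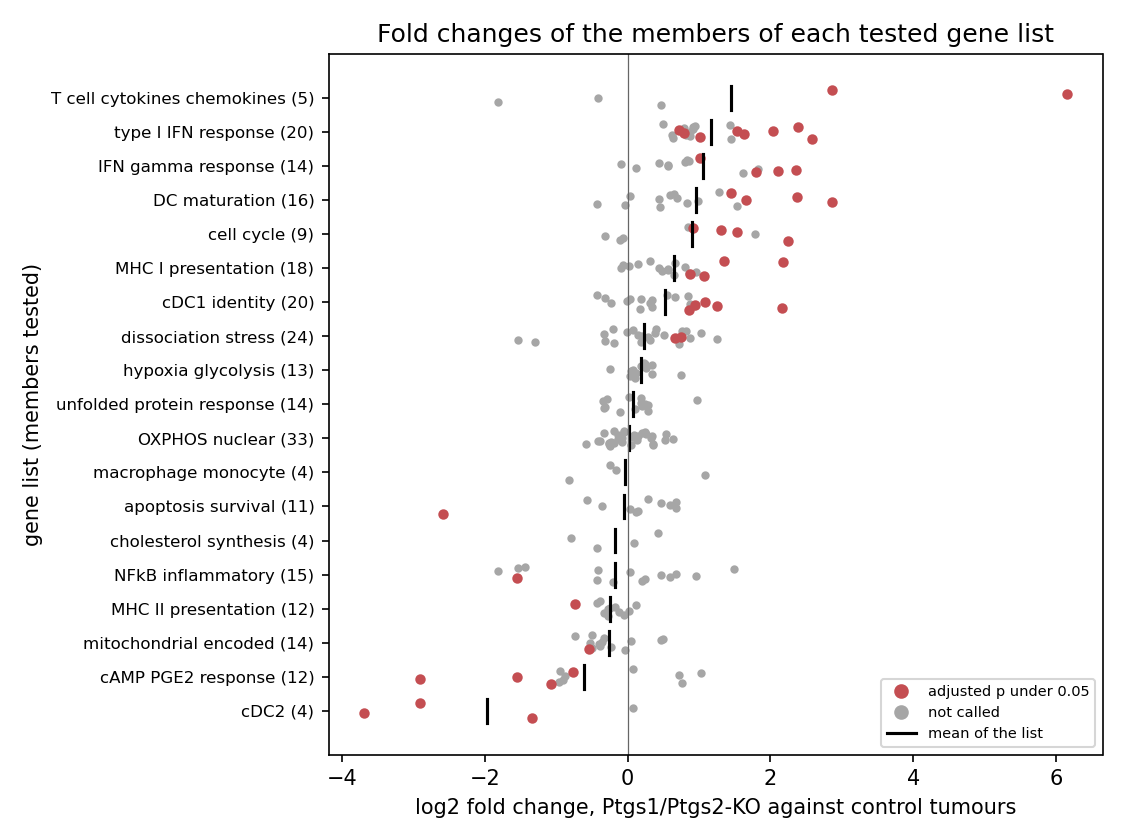
Log2 fold change (PGE2-deficient against control tumours) of each tested member of the 19 tested gene lists, with called genes in red, other genes in grey and the mean of each list as a bar. All 20 members of the type I interferon list lie above 0, and the means run from −1.96 for the cDC2 list to 1.45 for the T cell cytokine list.

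Lists of antigen presentation by MHC class II and of mitochondrially encoded RNA were slightly lower. In the former 1 of 12 tested members fell (1 adjusted over the list alone), the lysosomal protease gene Ctss (−0.73, adjusted p = 0.0448). The mean log2 fold change was −0.24 (camera adjusted p = 0.0305; adjusted p = 0.179 with an estimated correlation), and the list kept its call in 14 of 20 alternatives, losing it without PGE2-deficient mouse 3 or control mouse 4. In the latter 1 of 14 fell (2 adjusted over the list alone), mt-Nd2, a subunit of respiratory complex I (−0.54, adjusted p = 0.0416). The mean was −0.25 (camera adjusted p = 0.0058; adjusted p = 0.305 with an estimated correlation), and −0.17 without control mouse 2. Ctss (−0.86 to −0.61) and mt-Nd2 (−0.66 to −0.49) kept their calls in 3 and 2 of the 8 fits without a mouse. Without the 9 libraries with markers of other cells the class II list (−0.25, adjusted p = 0.06), Ctss (−0.55, adjusted p = 0.366) and mt-Nd2 (−0.54, adjusted p = 0.235) were not called.

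Including the macrophage list, 7 tested lists were not called. Hypoxia and glycolysis genes had a mean log2 fold change of 0.19 over 13 members (adjusted p = 0.22), with Pfkp at 0.75 (adjusted p = 0.0772) and Aldoa at 0.34 (adjusted p = 0.571). Inflammatory NF-kB targets had a mean of −0.18 and a median of 0.03 over 15 members (adjusted p = 0.583), of which Il1b fell (3 higher and 4 lower adjusted over the list alone). Unfolded protein response genes had a mean of 0.08 over 14 members (adjusted p = 0.641), with Manf at 0.98 (adjusted p = 0.147) and Hsp90b1 at 0.28 (adjusted p = 0.532). Cholesterol synthesis genes had a mean of −0.18 over 4 (adjusted p = 0.731), with Pmvk at −0.80 (adjusted p = 0.372) and Srebf2 at 0.42 (adjusted p = 0.498). Apoptosis and survival genes had a mean of −0.05, a median of 0.14 and an upward camera direction over 11 members (adjusted p = 0.856), of which Bcl2l11 fell, also adjusted over the list alone. Without a count filter this list was called higher (0.56, adjusted p = 0.0242). Nuclear genes of oxidative phosphorylation had a mean of 0.02 over 33 members (adjusted p = 0.856), with Ndufa6 at −0.58 (adjusted p = 0.0972) and Atp5b at 0.53 (adjusted p = 0.118).

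Across the 19 tested lists of 30 fixed, camera with its preset correlation called 8 higher and 4 lower. A split of the mice that balanced the groups still gave 8 list calls in this way, so the number of calls is weak evidence. With an estimated correlation the calls of type I interferon and cDC2 genes held. The directional test of fry, which asks whether a list moves on balance without comparing it with other genes, called 8 (5 higher and 3 lower).

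The 11 lists with fewer than 3 tested members were summarised as scores, the mean log2(CPM + 1) over all measured members. For T cells the score was 1.26 ± 1.30 in the control group and 2.29 ± 1.45 in the PGE2-deficient group, for NK cells 3.07 ± 0.932 and 3.69 ± 0.832. It was for B and plasma cells 2.04 ± 0.871 and 2.37 ± 1.27, and for neutrophils, measured by Hdc alone, 1.05 ± 2.09 and 2.54 ± 1.80. For pDC it was 3.15 ± 2.33 and 1.08 ± 0.326, and for Langerhans cells 2.24 ± 1.52 and 0.920 ± 1.23. It was for mast cells and basophils, measured by Kit alone, 7.04 ± 0.679 and 6.76 ± 0.565, for melanoma cells 2.22 ± 1.93 and 0.326 ± 0.652, for stroma 2.92 ± 0.826 and 2.00 ± 1.01, and for prostaglandin genes 3.68 ± 0.472 and 3.38 ± 0.521 (n = 4 mice each). The exact permutation p ran from 0.114 for pDC to 0.686 for B and plasma cells. Scores of neutrophils and melanoma cells rest on very few counts. In the control and PGE2-deficient groups these were 2 and 4 of Hdc, 6 and 1 of Dct and 3 and 0 of Pmel. The red blood cell list had 0 members in the table. Of tested members in these lists besides Tcf4, Klrk1 (0.31, adjusted p = 0.722), Kit (−0.41, adjusted p = 0.63), Alox5ap (−0.22, adjusted p = 0.564) and Ptges3 (0.22, adjusted p = 0.753) were not called.

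No score of the 29 measured lists passed the adjustment, in a design whose smallest exact p is 0.0286. That value was reached by 6 lists (adjusted p = 0.138 for each). In the control and PGE2-deficient groups the type I interferon score was 4.69 ± 0.696 against 6.26 ± 0.372, the cell cycle score 3.58 ± 0.601 against 5.16 ± 0.574 and the cDC1 score 6.18 ± 0.181 against 6.98 ± 0.201. The MHC class I score was 7.35 ± 0.191 against 8.02 ± 0.270, the apoptosis score 5.32 ± 0.238 against 5.91 ± 0.279, and the MHC class II score 9.38 ± 0.151 against 9.10 ± 0.0624.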

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

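All tests in this part that weigh explanations were chosen after the results were seen. Of the 35 splits of the 8 mice, 1, the real one, gave as many called genes, with 103 against 3 in the highest other split. This is the smallest share that 35 splits allow, so chance assignment of the mice is argued against but not excluded. Every other split mixes the 2 groups, which by itself lowers its calls. For the gene lists the real split also gave the most (1 of 35 splits), but only by 1 list, with 12 against 11 in the highest other split. Splits with 2 mice of each group on either side, where a group difference cancels, still called up to 8 lists. The split with 8 lists called 0 genes. List calls with the preset correlation thus also arise without the group difference, and their number is weak evidence.

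The 47 genes lower with PGE2-deficient tumours came with counts of macrophage, pDC and cDC2 markers in control pools, although the sort on CD103 without CD11b should remove most such cells. Macrophages and pDC as the whole cause are argued against: without the 9 libraries that held markers of macrophages, pDC or T cells, the median log2 fold change of all 47 was −1.10 against −1.06, a share of 1.04 (95% bootstrap interval over genes 0.83 to 1.27), with 47 of 47 in the same direction. Of these, 35 pass the count filter there, on which the test was first run with the same outcome, and the loss of calls to 24 is about that of removing as many libraries at random (median 21, from 6 to 38 in 50 draws). Cells like cDC2 cannot be told apart from a change within cDC1: with control levels extrapolated to 0 counts of Cd209a, Clec10a, Mgl2 and Sirpa, a share of 0.73 of the change remained, under the 0.75 set as the bar against such cells, and lower genes followed these markers between pools of a mouse (median r 0.26, one-sided permutation p = 0.0065). Ifitm1 had 50 to 443 counts in every control library and 0 to 105 in the others, and an effect of tumour PGE2 on cDC1 remains a hypothesis that this design cannot separate from a different mix of cells within the gate.

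Ccl5 was higher with PGE2-deficient tumours in a few pools, and T cells and NK cells, which also express it, may have been sorted with the cDC1 despite the gate on CD11c, MHC-II and CD103. T cells as the whole cause are argued against, because 78.2% of the group's 840 counts lay in the 8 libraries without a T cell receptor or CD3 count, and the library with the most such counts (29) had 0 Ccl5. When NK markers were added in a later version of the test, only 3 of 11 libraries were free of any T or NK marker count and held 12.6% of Ccl5 (106 counts), so the 2 sources together cannot be told apart from cDC1 expression. The NK markers were Gzmb, Klrb1c and Klre1, and the 3 libraries with the most Ccl5 held 685 Ccl5 and 14 T cell counts. Expression of Ccl5 by part of the cDC1 stays open as a hypothesis.

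Cell cycle genes were higher with PGE2-deficient tumours, whose libraries were deeper on average. After thinning every mouse to 101017 counts, the mean log2 fold change over 9 genes kept a share of 0.91 (0.78 to 0.96, mean of 20 draws, around which the single draws used first varied). Thinning leaves the expected proportions of a mouse unchanged, so a high share could be foreseen. It cannot decide whether differences behind the depth, such as RNA content or capture, played a part. T cells cannot be told apart as a contributor: without the 3 libraries of this group with T cell counts, a share of 0.74 remained. The interval was 0.13 to 0.89 over genes, with 6 of 9 genes positive. Libraries were dropped from this group alone, and a control library with 11 T cell counts was kept. A first version on the members that passed the count filter had left T cells excluded, and it was replaced because it left out members of the list. More division among cDC1 is a hypothesis that stays open beside T cells and differences behind the depth.

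Single mice stood apart from the other 3 of their group in 13 of 240 groups of values, where 12 are expected by chance. In control mice these were Casp6 at 240.9 CPM in mouse 3 (others 203.9 to 207.1), Irf1 at 0 CPM in mouse 3 (70.56 to 115.0), H2-K1 at 341.2 CPM in mouse 3 (471.6 to 501.8), Naaa at 309.7 CPM in mouse 2 (632.3 to 721.3), Ifi47 at 0 CPM in mouse 2 (54.88 to 60.22) and H2-Q7 at 46.01 CPM in mouse 1 (60.22 to 62.72). The neutrophil score was 4.187 in control mouse 2, from 2 counts of Hdc, and 0 in the others. In mice with PGE2-deficient tumours they were H2-K1 at 1744 CPM in mouse 2 (673.5 to 734.7), mt-Nd2 at 1526 CPM in mouse 3 (1172 to 1222) and Ptgs2 at 115.6 CPM in mouse 4 (0 in the others). There the cDC1 score was 6.677 in mouse 3 (7.054 to 7.091), and the melanoma score 1.305 in mouse 3, from 1 count of Dct (0 in the others). The 50 most abundant genes held 32.38% of counts in mouse 1 of that group (26.58 to 27.53).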

How the results depend on the processing

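The settings that drop libraries with markers of other cells, thin the counts or remove mitochondrial and ribosomal RNA were chosen after the data were seen. All 103 called genes kept their direction in every fit that tested them. Across alternatives, named genes stayed on their side of the threshold 1284 times, weakened past it 199 times and newly passed 32 times. Of these 32, 6 each were of Fscn1, Pfkp and Ccr2 and 5 of Irf1. The apoptosis list was called higher without a count filter (0.56, adjusted p = 0.0242, where all alternatives ran from 0.0242 to 0.984), which admits more members. Against 56 higher and 47 lower genes, no count filter gave 110 and 84 (13311 genes tested), at least 50 counts in 4 mice 29 and 19 (412 tested), technical replicates 2 and 3 alone 32 and 19, libraries without markers of other cells 18 and 6, and thinned mice 37 and 22 (33 to 54 and 20 to 37 over 20 draws). Lower genes numbered 79 with limma-voom and 28 with the mouse number as a block. The cause was not tested for these 2. Leaving out each mouse gave 31 to 67 higher and 23 to 45 lower genes. Against 8 lists higher and 4 lower, an estimated correlation gave 1 and 1, fry 5 higher, and the strict filter 2 lower. Shallow pools limit the analysis to 2076 of 13311 genes with counts.

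Some called values kept their direction and moved by over 1.5 times. With limma-trend on library means 14 named genes had smaller fold changes, among them Ccl5 (3.29), Cks1b (1.30) and Bcl2l11 (−1.30), and the cause was not tested. Without the libraries with markers of other cells, which leaves fewer members to test, list means were 1.81 (type I interferon), 2.57 (T cell cytokines), 0.45 (dissociation) and −3.28 (cDC2). Over the same members in all libraries they were 1.38, 2.07, 0.33 and −2.64. From technical replicates 2 and 3 alone the T cell cytokine list was 2.35, the dissociation list 0.45 and Tlr3 2.03. The strict filter, which also leaves fewer members, gave 1.39 for cell cycle, 0.57 for dissociation and −0.95 for cyclic AMP genes. No filter gave 1.43 for cell cycle, and thinning 0.36 for dissociation.

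No called gene or list reversed. The following uncalled results did, and the cause was not tested. The NF-kB list turned positive with the strict filter (0.16), limma-trend (0.075), marker libraries left out (0.50) and thinning (0.068), from −0.29 to 0.13 over the fits without a mouse. Its score difference was 0.0096 with pseudocount 5, 0.31 with library means and from −0.25 to 0.11 without a mouse. The hypoxia list was −0.21 and the macrophage list −2.03 (called lower) without a filter, which admits more members. OXPHOS turned in rank direction with means of 0.031 (limma-trend) and 0.011 (technical replicates 2 and 3). Without a mouse, list means ran from −0.072 to 0.17 (unfolded protein response), −0.15 to 0.072 (cholesterol), −0.11 to 0.0095 (apoptosis), 0.023 to 0.091 (OXPHOS) and −0.27 to 0.36 (macrophage). Cd86 was 0.21 with limma-trend, 0.072 with limma-voom, 0.013 with the block, 0.34 without marker libraries, 0.085 thinned and from −0.21 to 0.24 without a mouse. Batf3 was −0.13 without marker libraries and Klrk1 −0.067 with technical replicates 2 and 3. Without a mouse Ptges3 ran from −0.10 to 0.39 and Kit from −0.62 to 0.0011. With library means the prostaglandin score differed by 0.14 and the cholesterol score by 0.0021. Without a mouse score differences ran from −0.036 to 0.18 (unfolded protein response), from −0.26 to 0.73 (B and plasma cells) and from −0.51 to 0.027 (mast cells).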

Other observations

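The genes and the test in this part were chosen after the data were seen, so no test of the gene families as sets is given. All 4 tested members of the Ifitm family, membrane proteins that restrict virus entry, were called lower with PGE2-deficient tumours. Besides Ifitm1 and Ifitm6, Ifitm2 fell from 2140 ± 522 to 979 ± 274 CPM (−1.12 ± 0.20, adjusted p = 0.00265) and Ifitm3 from 2460 ± 314 to 1385 ± 393 CPM (−0.81 ± 0.18, adjusted p = 0.0134; n = 4 mice each). Of 7 tested members of the HIN200 family of nuclear DNA-binding proteins 5 were called higher. Among them Ifi211 rose from 588 ± 77.6 to 1281 ± 378 CPM (1.14 ± 0.21, adjusted p = 0.00262) and Ifi205 from 1654 ± 241 to 2708 ± 748 CPM (0.72 ± 0.18, adjusted p = 0.0325). The Ifitm genes lie together on chromosome 7 and the HIN200 genes on chromosome 1, and each family is similar in sequence, so the counts of its members are not independent.

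Further called genes outside the lists were Fth1, the heavy chain of the iron store ferritin, which fell from 2495 ± 42.6 to 1086 ± 79.5 CPM (−1.20 ± 0.13, adjusted p = 1.54e-05), and Txn1, which encodes thioredoxin and rose from 431 ± 137 to 1196 ± 286 CPM (1.47 ± 0.22, adjusted p = 0.000496). Prdx1, a peroxiredoxin, rose from 596 ± 139 to 992 ± 211 CPM (0.74 ± 0.20, adjusted p = 0.0441). Of 83 tested genes of ribosomal proteins 8 were called lower and 80 had a negative fold change, with a mean of −0.31. With DESeq2 size factors and with upper quartile factors all 103 called genes kept their direction. Log2 fold changes of tested genes shifted by a median of 0.002 and −0.066, small beside the mean of −0.31. The mean of the ribosomal protein genes under these factors is not given here.

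Maturation genes varied widely between pools of a mouse. Il12b had 36 and 1 counts in the 2 pools of PGE2-deficient mouse 2, and Ccr7 had 28, 33 and 0 counts in those of control mouse 4, while Il12b had an even 30, 48 and 45 counts in PGE2-deficient mouse 1. The within-mouse SD of the score over the 16 tested maturation genes was 1.88, against 0.92 for interferon gamma, 0.84 for type I interferon, 0.50 for cDC1 and 0.34 for MHC class I genes. One hypothesis is that mature cells were caught in some pools of 10 cells and not in others. The SD lay at percentile 100 of 1000 random lists of matched abundance (median 0.59, highest 1.02), but random lists are not co-regulated, so this cannot tell uneven capture of mature cells from any other shared variation of these genes.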
